A study of Homo sapiens with 29 samples.

How the data were processed

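Total RNA of HepG2 cells was labelled as biotinylated cRNA and hybridized to Affymetrix arrays, 13 of CCL-treated and 16 of untreated cells, in 11 groups defined by arm and time in the labels. The deposited values are log2 expression per probe set, made with Affymetrix Expression Console 1.1 and RMA per the submitters' processing notes, and were used as they stand for 53617 probe sets on 29 arrays. RMA equalizes the distributions of arrays normalized together, and the array medians differ here, so the arrays were not all normalized together, but which ones were is not stated. No raw intensity or detection values were used here, and for arrays the depth behind a value is unknown.

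Probe sets were named from the array's probe table (HuGene 2.0 ST). A single gene symbol was given for 16098 probe sets, all matched by gene ID to the RefSeq annotation of GRCh38.p14, and none had several symbols. The other 37519 had no symbol in the table held here and were not analysed here, apart from a count in the closing section. Of 14884 named genes, 779 had more than 1 probe set, and the probe set with the highest mean over all arrays stood for the gene. The 6529 genes above log2 5 on at least 2 arrays were tested. Some genes that were to be reported whatever they showed, among them NQO1, HSPA5, CDKN1A, GADD45A, MDM2 and CYP1A1, had no named probe set and were not analysed here, and DDIT3 lay below the filter.

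A linear model with 1 mean per group was fitted to all 29 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that groups of 2 or 3 arrays shared 1 estimate of the spread of each gene. Contrasts were CCL against untreated cells at each of 5 times, the mean of these 5 differences, an F-test of whether the CCL effect differed between the 5 times, the difference of each later effect from that at 6 h, and untreated cells at each time against 0 h. P-values are two-sided and adjusted by Benjamini and Hochberg over the 6529 genes of each comparison. A gene is said to be called, to rise or to fall where its adjusted p was under 0.05, and errors are standard errors from this model. The labels do not say whether arrays of a group come from separate cultures, so p-values measure only the spread between these arrays. The mean SD between arrays of a group ran from 0.18 (untreated 48 h) to 0.5 (untreated 18 h). The errors use 1 spread per gene, pooled over all 29 arrays. They can be too small for groups that vary more and too large for groups that vary less. For the replication gene GINS1 at 48 h the error was 0.465, while its 2 CCL arrays had an SD of 1.921. Fitting the compared arrays alone changed the calls from 428 to 0 at 48 h and from 81 to 660 at 12 h. Contrasts of CCL with untreated cells at different times use different arrays, while those of untreated cells with 0 h share the 0 h arrays, so no correlation between the latter is given.

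The set number could pair arrays of the arms. Residuals of arrays with the same number and time correlated above 0.1 in 9 of 12 pairs (-0.0657 to 0.444). However, the own number correlated best in only 7 of 12. Pairing was therefore not taken as established, and models with set as a block are given only as alternatives. Sets still differed. On the second principal component after quantile normalization (13.99% of the variance), set 3 lay highest in every group that holds it. At 6 h, sets 1, 2 and 3 lay at -1.585, 0.8834 and 11.53 in untreated cells. In CCL-treated cells they lay at -1.661, 0.1439 and 15.65. Set 3 is missing from CCL-treated cells at 24 h and 48 h, and set 2 from untreated cells at 18 h. The main model does not adjust for this. No test for single distant arrays was made.

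Of 41 gene lists (796 genes), 462 genes had a named probe set, 15 of them through an older symbol, and 382 were tested. The 35 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 175 tests of 35 lists at 5 times, and for the mean over the times over 35 tests. AHR targets, endothelial, fibroblast and squamous markers, proteasome subunits and replication-dependent histones had at most 1 tested member and were not tested. Camera asks whether a list moved relative to other genes. It was repeated with the correlation estimated from the residuals of each list, and 2 of the 64 calls held, immediate early genes at 6 h and leukocyte markers at 48 h. By fry, which asks whether the genes of a list move on balance one way and does not compare lists with other genes, 30 list-time tests were called. Members were counted at the threshold over all genes and adjusted over the list alone. Some genes, such as IER3, VEGFA, MYC and TBX3, sit on more than 1 list.

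Genes named in the text follow a rule set before the data were examined, as were the lists, the comparisons, the tests, the filter and the first group of alternatives. The rule names, at each time, the 6 highest and 6 lowest log2 fold changes among called genes whose CCL arrays all lay on one side of the untreated arrays, genes called in the same direction at all 5 times, the 4 members with the lowest p of each called list and members needed to describe a count, 22 genes fixed by name, the 5 highest and 5 lowest at 48 h against 0 h in untreated cells (none were called), and the 6 genes with the lowest p in the F-test. Genes outside it are said to be chosen after their values were seen. Fold changes of probe sets that overlap another gene, as of MIR3189 within GDF15, can measure either. Log2 fold changes are differences of RMA values, which compress large changes of dim genes.

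The alternatives set beforehand were a fixed and a random set block (statmod 1.5.0), no filter and a filter at log2 6, the mean of a gene's probe sets, quantile normalization of all 29 arrays, median centring, a mean-variance trend with robust estimation, array weights, a model of the compared groups alone, each array left out in turn, 0 h cells as control, a 2-fold minimum, and sets 1 and 2 alone. A left-out array leaves some groups with 1 array, which is then assumed to vary like the others. The alternatives added after the data were seen are named in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

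The procedure was tested on simulated data with 200 genes changed, the group sizes of these arrays and the spread of each gene estimated from them. The simulated noise was independent between arrays, with 1 spread per gene in all groups. It held no array-wide shift, unequal group spread or set difference, all of which these arrays show. The shares and false calls below therefore hold for such simpler data. Of genes changed 2-fold, 64.2% were recovered at 6 h, 59.7% at 12 h, 43.3% at 18 h, 47.8% at 24 h, 40.3% at 48 h and 100% in the mean over the times, with 3 to 9 false calls per comparison, and of genes changed 4-fold at least 89.4% were recovered. Of genes changed 1.5-fold, at most 11.9% were recovered at a single time and 74.6% in the mean. In these data, simulated with noise independent between genes, 1 list moved by 0.25 in all CCL arrays was called at 18 h, 48 h and in the mean and not at the other times, and 0 of the other lists were called by camera. The F-test called 0 genes, whose simulated change was the same at all times, so its power was not tested.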

Results

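HepG2 cells, an established line from a human liver tumour, were left untreated or treated with CCL, the abbreviation in the labels for the herb Cratoxylum cochinchinense Lour. Their total RNA was measured on 29 Affymetrix arrays. Untreated cells were sampled at 0, 6, 12, 18, 24 and 48 h, and CCL-treated cells at 6, 12, 18, 24 and 48 h. Each arm had 3 arrays at 6 h and at 12 h. The 18 h time had 3 CCL and 2 untreated arrays, 24 h and 48 h each had 2 CCL and 3 untreated arrays, and 0 h had 2 untreated arrays. The labels number the arrays as sets 1 to 3 and say neither what a set is nor what dose was given. They name no vehicle for the untreated cells. Effects given below as those of CCL therefore cannot be told apart from those of a solvent or of handling during treatment. The number of arrays limits the precision of every value below. The series states that fold changes of genes among time points were sought in treated and untreated cells.

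The median log2 value over all probe sets of an array ran from 2.29 in untreated cells at 18 h (set 1) to 3.39 in CCL-treated cells at 18 h (set 3). For 17 arrays it lay between 2.94 and 3.07, and for the 6 arrays of 12 h, both arms alike, between 2.51 and 2.54. The 6 remaining arrays stood apart. Of the untreated ones, 18 h set 1 lay at 2.29 and 24 h set 1 at 2.83, and of the CCL arrays 6 h set 1 lay at 2.65, 18 h set 3 at 3.39, 24 h set 1 at 2.83 and 48 h set 1 at 2.75. Because of these differences, values after quantile normalization are given beside many of those of the deposited values. After quantile normalization the first principal component held 32.2% of the variance. All 13 CCL arrays (3.402 to 49.9) lay above all 16 untreated arrays (-16.45 to -4.76). On the first component of the deposited values, which is a separate axis, the arms overlapped. There CCL arrays ran from -30.16 to 47.84 and untreated arrays from -23.48 to 44.69.

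**Figure D1:**
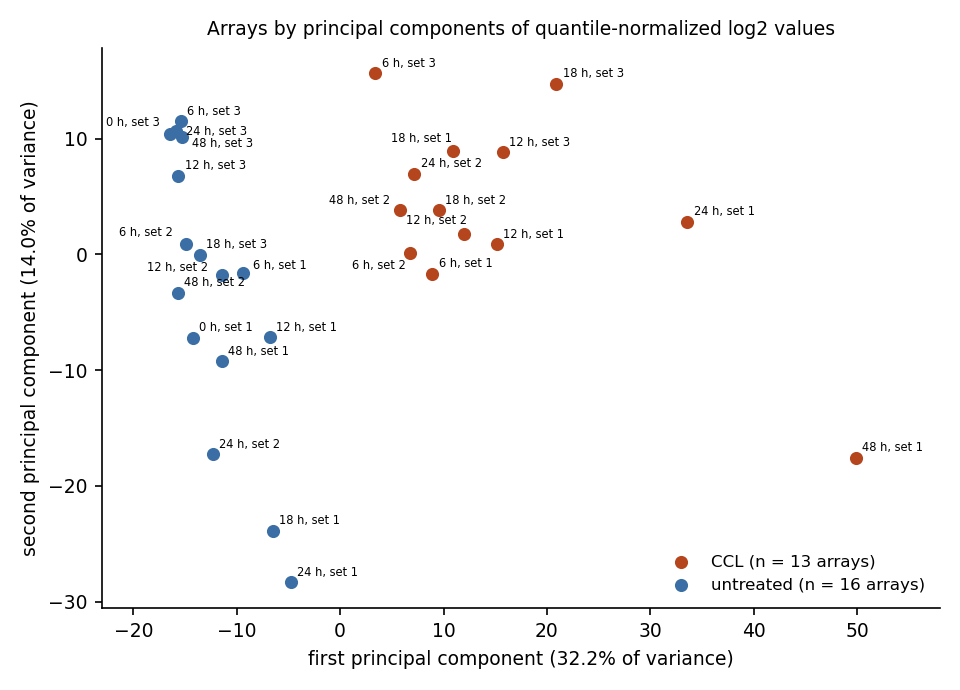
First and second principal components of the 29 arrays after quantile normalization, with 1 point per array, coloured by arm and labelled by time and set. CCL arrays lie at 3.402 or above on the first component and untreated arrays at -4.76 or below, and the set 1 CCL arrays of 48 h (49.9) and 24 h (33.6) lie farthest out.

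Averaged over the 5 times, IL11, which encodes a cytokine of the interleukin-6 family, was higher with CCL by a mean log2 fold change of 3.25 ± 0.17 (SE, 13 CCL arrays against time-matched untreated arrays, adjusted p = 4.32e-13). LIF, of the same cytokine family, rose by 2.27 ± 0.18. IGFBP1, encoding a binding protein of insulin-like growth factors, was higher by 3.04 ± 0.23, and the long non-coding RNA UCA1 by 3.02 ± 0.22. DUSP5, encoding a nuclear phosphatase of ERK kinases, rose by 2.71 ± 0.20, and the stress-induced cytokine gene GDF15 by 2.18 ± 0.13. The chemokine gene CCL20, unrelated to the herb's abbreviation, rose by 2.17 ± 0.25, the lipid synthesis gene GPAT3 by 2.05 ± 0.18 and SNAI2, encoding a repressor of epithelial genes, by 1.95 ± 0.15. In the other direction, MAP2K6, encoding a kinase that activates p38, changed by -2.15 ± 0.22 and TXNIP, encoding a thioredoxin-binding protein, by -1.54 ± 0.32. The alcohol dehydrogenase gene ADH6 changed by -1.42 ± 0.23, and the mitotic kinesin genes KIF20A and KIF11 by -1.33 ± 0.20 and -1.18 ± 0.21. The liver transcription factor genes ONECUT1, FOXA1 and GATA6 fell by 1.12, 0.80 and 0.76. MYC rose by 0.48 ± 0.12 and ATF3 by 0.84 ± 0.23. The genes ALB (-0.06 ± 0.08), AFP (-0.14 ± 0.09), CCND1 (-0.09 ± 0.10), HSPA1A (0.22 ± 0.13) and HMOX1 (0.58 ± 0.41) were not called over the 5 times or at any single time. In all, 885 of 6529 genes were called higher and 721 lower by limma, against 1075 and 1237 after quantile normalization. Both called 1592 genes in the same direction. With any single array of the 5 times left out, the highest adjusted p was 4.94e-12 for IL11 and 3.83e-07 for MAP2K6. For 3 of these genes a second, dimmer probe set gave a smaller mean log2 fold change, 0.37 for DUSP5, 0.69 for UCA1 and -0.09 for TXNIP.

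Only 8 genes were called higher at each of the 5 times, namely IL11, GDF15, DUSP5, LIF, JAG1, IER3, SAT1 and SHB, and none was called lower at each (19 and 0 after quantile normalization). JAG1, encoding a Notch ligand, was raised least at 48 h (1.32 ± 0.29) and most at 18 h (2.302 ± 0.292). The early response gene IER3 ranged from 1.40 at 48 h (0.82 without CCL 48 h set 1, 1.99 without set 2) to 1.87, SAT1, encoding a polyamine acetyltransferase, from 0.90 to 1.91, and the adaptor gene SHB from 0.92 to 1.40. SHB was not called at 18 h or 24 h after quantile normalization. Direction was shared more widely than calls. Of the 1606 genes called over the 5 times, 697 were higher and 417 lower at every time. After quantile normalization these were 882 and 944 of 2312. The genes were picked by the mean of the same 5 differences, so such agreement is partly built in, and no value by chance was computed. Across the 6529 genes, the log2 fold changes of any pair of times correlated with Pearson's r between 0.389 (6 h with 18 h) and 0.748 (12 h with 48 h), median 0.634. They correlated with Spearman's rho between 0.303 and 0.713, over 10 pairs. These pairs share no arrays, and genes are not independent replicates. Of the genes called higher, 66 were shared between 12 h and 18 h (8.36 by chance), 154 between 18 h and 24 h (20.4 by chance) and 65 between 24 h and 48 h (2.21 by chance). Of the genes called lower, 9 were shared between 24 h and 48 h (1.62 by chance).

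**Figure D2:**
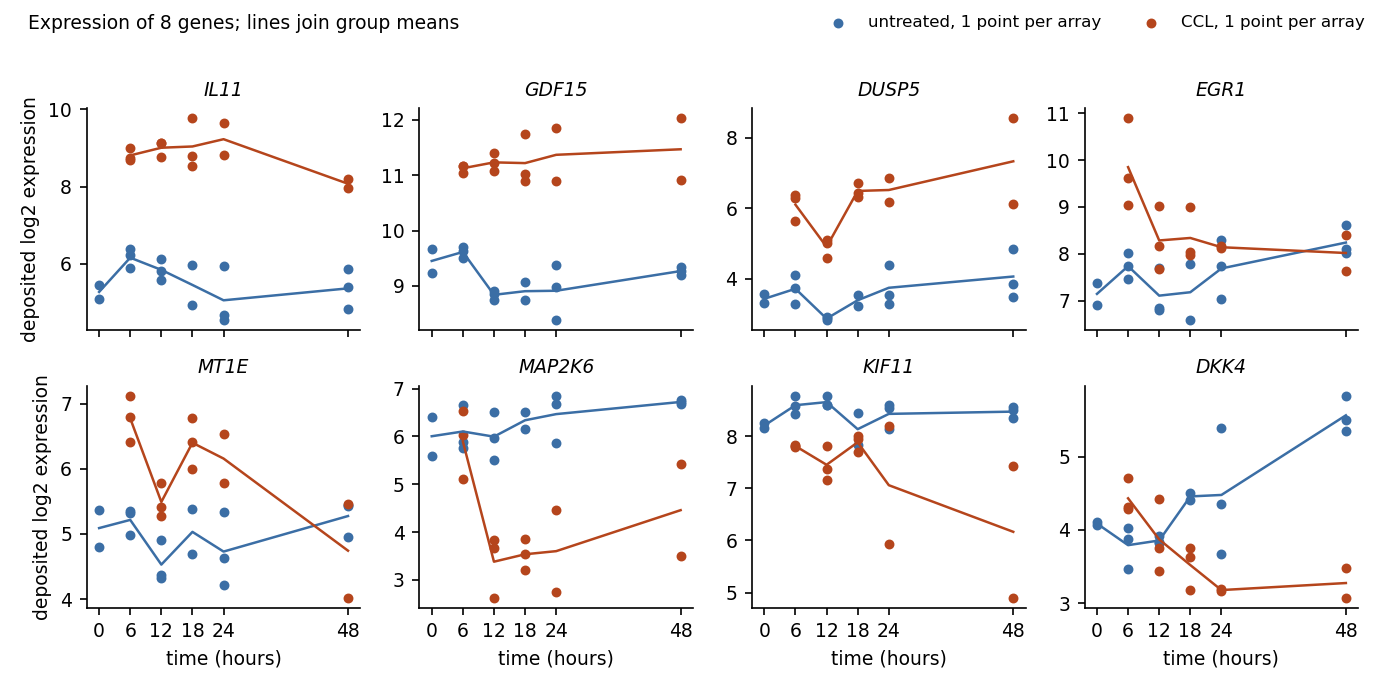
Deposited log2 expression against hours for IL11, GDF15, DUSP5, EGR1, MT1E, MAP2K6, KIF11 and DKK4, with 1 point per array and lines joining the means of the CCL and the untreated arrays. IL11 is higher with CCL by 2.65 at 6 h and 4.17 at 24 h, EGR1 by 2.11 at 6 h only among called times, and DKK4 changes by -2.29 at 48 h.

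Groups of genes moved together in this mean. Immediate early genes, transcribed within minutes of a stimulus, rose as a list (median log2 fold change 0.85 over 20 genes, adjusted p = 2.64e-13, adjusted p = 0.202 with an estimated correlation), led by DUSP5, IER3, FOSL1 (1.67 ± 0.18) and SPRY4 (1.39 ± 0.16). Over all genes 16 of the 20 were called higher, and 16 adjusted over the list alone. G2 and M phase genes fell (median -0.69 over 23 genes, adjusted p = 2.01e-13, adjusted p = 0.374 with an estimated correlation), and 22 were called lower over all genes and 22 adjusted over the list alone. Among them were NUSAP1 (-0.90 ± 0.13) and CCNB1 (-0.70 ± 0.14). G1/S and DNA replication genes fell (median -0.48 over 23 genes, adjusted p = 3.52e-09, adjusted p = 0.392 with an estimated correlation), with 17 called lower over all genes and 17 adjusted over the list alone. Cholesterol synthesis and uptake genes fell (median -0.50 over 14 genes, adjusted p = 5.56e-06, adjusted p = 0.392 with an estimated correlation), with 11 called lower and 12 adjusted over the list alone. Among them were IDI1 (-0.81 ± 0.12), SQLE (-0.71 ± 0.14) and MSMO1 (-0.91 ± 0.18). Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose (median 0.60 over 16 genes, adjusted p = 3.83e-05, adjusted p = 0.392 with an estimated correlation), with 11 called higher and 12 adjusted over the list alone. All 18 of the 35 lists called in this mean lost the call with an estimated correlation, for which the lowest adjusted p was 0.202.

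Hypoxia targets were not called as a list at any time (lowest adjusted p = 0.0857), nor were p53 targets (0.0627), ribosome biogenesis and MYC targets (0.0691), ER chaperones (0.0975), interferon-stimulated genes (0.215), heat shock and HSF1 targets (0.245), cholangiocyte and progenitor markers (0.393), glycolysis (0.415), fatty acid oxidation and PPARA targets (0.42), cytosolic ribosomal proteins (0.42) or housekeeping genes (0.809). Members did change within some of these. Over the 5 times, 5 hypoxia targets were called higher and 1 lower, and 4 p53 targets higher and 1 lower. VEGFA, a hypoxia target that is also on the ATF4 list, rose by 0.65 ± 0.17.

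At 6 h, the earliest time, CCL raised genes of the immediate early response. IL11 was 6.26-fold higher (log2 fold change 2.65 ± 0.35, 3 arrays per arm, adjusted p = 0.000328), and DUSP5 and LIF were higher by 2.39 ± 0.41 and 2.18 ± 0.37. The transcription factor genes EGR1 and JUNB rose by 2.11 ± 0.42 (adjusted p = 0.0195) and 1.98 ± 0.33 (adjusted p = 0.00476). MT1E, encoding a metal-binding metallothionein, rose by 1.56 ± 0.33 and MCL1, encoding an anti-apoptotic BCL2 relative, by 1.11 ± 0.21. The genes called lower were WDCP (-1.49 ± 0.30) and ASB16-AS1 (-1.33 ± 0.27). Of 6529 genes 18 were called higher and 2 lower. Called or not, 407 genes higher and 901 lower had all CCL arrays on one side of all untreated arrays, 20% of genes against 10% by chance. After quantile normalization 59 were called higher and 26 lower, so the share higher went from 90% to 69.4%. With set as a fixed block 63 were called higher and 45 lower. IL11, LIF, JAG1 and JUNB were called whichever array of the compared groups was left out. The other 10 named genes called at this time lost the call without at least 1 array of the compared groups. ASB16-AS1 lost it whichever of them was left out (adjusted p from 0.0539 to 0.15), so its loss points to no particular array. Leaving out untreated set 1, 2 or 3 ended 7, 9 and 7 of the calls (adjusted p up to 0.204, reached by MT1E without set 2). Leaving out CCL set 1, 2 or 3 ended 5, 3 and 7 (adjusted p up to 0.198, reached by EGR1, IER3 and MT1E without set 3). The count of called genes was 8, 6 and 9 without untreated set 1, 2 or 3, and 9 without CCL set 3.

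Immediate early genes at 6 h were the list with the strongest response, all 20 members being higher (median 0.94, adjusted p = 1.81e-30). The call held with an estimated correlation (adjusted p = 0.0217), with 5 members called over all genes and 16 adjusted over the list alone. Metallothioneins rose (median 0.80 over 5 genes, adjusted p = 1.21e-07, adjusted p = 0.0972 with an estimated correlation), with 1 called and 4 adjusted over the list alone. Genes of TGF-beta signalling and epithelial-mesenchymal transition rose (median 0.91 over 10 genes, adjusted p = 4.37e-07, adjusted p = 0.317 with an estimated correlation), with 0 called by limma and 4 adjusted over the list alone. NF-kB and inflammatory targets rose too (median 0.59 over 8 genes, adjusted p = 1.87e-06, adjusted p = 0.208 with an estimated correlation), with 1 called and 4 adjusted over the list alone. NRF2 targets rose less (median 0.31 over 9 genes, adjusted p = 0.00268, adjusted p = 0.609 with an estimated correlation), a call lost without CCL 6 h set 3 (adjusted p = 0.0539). G2 and M phase genes were already lower (median -0.55, adjusted p = 1.35e-07, adjusted p = 0.559 with an estimated correlation), as were DNA repair genes (median -0.36 over 12 genes, adjusted p = 0.0134, adjusted p = 0.78 with an estimated correlation). The DNA repair call was lost without untreated set 2 (adjusted p = 0.0832) or CCL set 3 (adjusted p = 0.0634).

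By 12 h, IL11 (3.16 ± 0.35), IGFBP1 (3.10 ± 0.48, 8.59-fold, adjusted p = 0.000583, 3 arrays per arm) and UCA1 (3.08 ± 0.46) were the genes raised most. GDF15 rose by 2.39 ± 0.28 (adjusted p = 1.62e-05), MIR3189, a microRNA gene within GDF15, by 2.61 ± 0.44, and AQP3, encoding a water and glycerol channel, by 2.26 ± 0.45. HAMP, which encodes the iron hormone hepcidin, rose by 1.94 ± 0.39, and the homeobox gene DLX2 by 1.15 ± 0.19. MAP2K6 fell most (-2.62 ± 0.46, adjusted p = 0.00219), followed by GPR119 (-1.94 ± 0.45) and KIF20A (-1.73 ± 0.42). Also lower were the TXNIP relative ARRDC4 (-1.51 ± 0.38), SMLR1 (-1.46 ± 0.35) and IDI1, of isoprenoid synthesis (-1.39 ± 0.26). Calls numbered 68 higher and 13 lower. Called or not, 770 genes higher and 1399 lower separated the arms completely (33.2% of genes, 10% by chance). After quantile normalization there were 116 higher and 30 lower, and ARRDC4 was not called. With set as a fixed block there were 149 higher and 108 lower. Among the 28 named genes called at 12 h, 15 kept the call whichever array of the compared groups was left out, including IL11, IGFBP1, UCA1, GDF15, SNAI2, MAP2K6 and IDI1. Leaving out untreated set 1, 2 or 3 ended 10, 8 and 11 of the other 13 calls (adjusted p up to 0.24, SMLR1 without set 3). Without CCL set 1, 2 or 3 the losses were 11, 10 and 10 (adjusted p up to 0.268, ARRDC4 without set 3). The count of 81 called genes became 45, 45 and 28 without untreated set 1, 2 or 3 and 34, 35 and 47 without CCL set 1, 2 or 3.

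Immediate early genes remained raised at 12 h (median 0.86, adjusted p = 2e-16, adjusted p = 0.0972 with an estimated correlation), with 6 called and 13 adjusted over the list alone. G2 and M phase genes fell (median -0.84, adjusted p = 3.12e-14, adjusted p = 0.471 with an estimated correlation), with KIF20A and NUSAP1 called over all genes and 17 adjusted over the list alone. Cholesterol genes fell (median -0.54, adjusted p = 2.73e-05, adjusted p = 0.559 with an estimated correlation), IDI1 being the 1 called and 5 being called adjusted over the list alone. ATF4 and CHOP targets, not called at 6 h, rose (median 0.39, adjusted p = 0.000295, adjusted p = 0.55 with an estimated correlation) through GDF15 and STC2 (1.22 ± 0.28), with 3 adjusted over the list alone. Metallothioneins (median 0.88), NF-kB targets (0.46), NRF2 targets (0.32), TGF-beta genes (0.21), gluconeogenesis genes (0.42) and the BCL2 family (0.15) also rose as lists. Their adjusted p ran from 7.94e-06 to 0.0479, the lowest being adjusted p = 0.208 with an estimated correlation. DNA repair (-0.53), G1/S (-0.38), splicing factor (-0.34) and fatty acid synthesis genes (-0.33) fell, with adjusted p from 0.00121 to 0.0255, and adjusted p = 0.644 with an estimated correlation at the lowest. Without CCL 12 h set 3 the G1/S call was lost (adjusted p = 0.121), and without untreated 12 h set 1 the fatty acid call (adjusted p = 0.0586). The BCL2 family call was lost without untreated 12 h set 1 (0.0887), 24 h set 3 (0.0548) or 48 h set 1 (0.0507). It was also lost without CCL 12 h set 1 (0.11) or set 2 (0.0797) or 48 h set 1 (0.0528) or set 2 (0.0502).

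At 18 h, IGFBP1 was 15.3-fold higher with CCL (log2 fold change 3.93 ± 0.53, 3 CCL and 2 untreated arrays, adjusted p = 5.49e-05), against a median of all genes that itself was 0.415 higher. After quantile normalization, which removes that shift, IGFBP1 was higher by 3.64, CCL20 by 3.33 (3.72 ± 0.57 on deposited values) and UCA1 by 3.33. IL11 was higher by 3.20, AQP3 by 2.73 and SNAI2 by 2.71 (3.15 ± 0.36 on deposited values). STC2, encoding the secreted glycoprotein stanniocalcin 2, rose by 2.19 ± 0.31 and VEGFA by 1.73 ± 0.40. The aminoacyl-tRNA synthetase genes CARS1 and YARS1 rose by 1.29 ± 0.25 and 1.31 ± 0.28. MAP2K6 fell by 2.80 despite the shift, TMT1A by 1.70, DHRS2 by 1.21, SMLR1 by 1.18, MPV17L by 1.097 and ERAP2 by 1.06. Deposited values gave 803 genes called higher and 12 lower, while 2122 genes higher and 167 lower, called or not, separated the arms (35.1% of genes, 20% by chance). Quantile-normalized values gave 224 and 114, so the share higher went from 98.5% to 66.3%. Called in the same direction in both were 236 genes. Untreated set 1, the array with the lowest median, decided most of this. Without it 24 genes were called and 35 of the 47 named calls were lost, with adjusted p up to 0.687 (TBX3) and 0.31 for YARS1. Leaving out untreated set 1 or set 3 moved the log2 fold change on deposited values to 3.13 or 4.74 for IGFBP1, 2.27 or 5.17 for CCL20, 2.304 or 3.997 for SNAI2, 2.06 or 4.26 for AQP3 and 1.11 or 2.36 for VEGFA. Kept whichever array of the compared groups was left out were the calls of DUSP5, GDF15, GPAT3, IGFBP1, IL11, JAG1, LIF, MAP2K6, SAT1, SNAI2, STC2 and UCA1. The count was 2647 without untreated set 3 and 186 without CCL set 3, and leaving these out ended 4 and 18 named calls (adjusted p up to 0.127 for SMLR1 and 0.256 for TRIB3). Leaving out CCL set 1 or set 2 ended 3 and 2 (adjusted p up to 0.0931 for TMT1A and 0.072 for SMLR1).

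Targets of ATF4 and CHOP were the list raised most at 18 h (median 1.39, adjusted p = 1.09e-05, adjusted p = 0.478 with an estimated correlation), with 11 of 16 called and 12 adjusted over the list alone (5 called after quantile normalization). Besides GDF15 and STC2 these included SESN2 (1.19 ± 0.23) and TRIB3 (1.00 ± 0.31), and ATF3 itself was not called (1.43 ± 0.55, adjusted p = 0.0776). Immediate early genes rose (median 1.15, adjusted p = 1.61e-05, adjusted p = 0.478 with an estimated correlation). Of these 12 were called, 14 adjusted over the list alone, and 5 were called after quantile normalization. Aminoacyl-tRNA synthetases rose (median 0.72 over 13 genes, adjusted p = 0.00349, adjusted p = 0.596 with an estimated correlation), with 5 called and 8 adjusted over the list alone, a list call lost without untreated 18 h set 3 (adjusted p = 0.169). NF-kB targets rose (median 0.66, adjusted p = 0.0121, adjusted p = 0.52 with an estimated correlation), lost without the same array (adjusted p = 0.0562). G1/S genes (median -0.19, adjusted p = 1.02e-10, adjusted p = 0.478 with an estimated correlation) fell relative to the raised median of all genes. So did cholesterol genes (-0.19, adjusted p = 1.35e-07, adjusted p = 0.478 with an estimated correlation) and G2 and M phase genes (-0.13, adjusted p = 1.85e-07, adjusted p = 0.566 with an estimated correlation), with 0 members of each of these 3 lists called by limma. For 6 further lists called lower relative to other genes the median log2 fold change on deposited values was positive. All 6 medians turned below 0 (-0.06 to -0.27) without untreated 18 h set 1, 4 of them also without CCL 18 h set 3 and that of DNA repair without CCL 18 h set 2. Without untreated 18 h set 3 those of G2 and M phase genes (0.01) and cholesterol genes (0.10) turned above 0. Of these, plasma protein, fatty acid synthesis and DNA repair genes had medians of 0.00, 0.05 and 0.05, and of -0.16, -0.43 and -0.37 after quantile normalization. Their adjusted p was 2.73e-05, 0.000827 and 0.00349 (adjusted p = 0.478, 0.559 and 0.688 with an estimated correlation). Hepatocyte transcription factors (median 0.06, adjusted p = 0.0255), acute phase proteins (0.14, adjusted p = 0.0372) and WNT targets (0.21, adjusted p = 0.0479) were called lower on deposited values. They were not called after quantile normalization (adjusted p = 0.0899, 0.323 and 0.181), and reached adjusted p = 0.55, 0.667 and 0.644 with an estimated correlation. The mean log2 fold change, unlike the median, was negative for DNA repair genes (-0.00339) and hepatocyte transcription factors (-0.02).

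CCL raised IL11 18.0-fold at 24 h (log2 fold change 4.17 ± 0.39, 2 CCL and 3 untreated arrays, adjusted p = 3.82e-07) and UCA1 by 3.96 ± 0.51. IGFBP1 rose by 3.60 ± 0.53, VNN1, encoding a pantetheinase, by 3.08 ± 0.50 and GPAT3 by 2.91 ± 0.43. The membrane protein gene CD109 rose by 2.57 ± 0.35, the metallothionein genes MT2A and MT1X by 1.40 ± 0.28 and 1.33 ± 0.27, and SQSTM1, encoding an autophagy receptor, by 1.24 ± 0.34. Among the genes that fell, ADH6 was 7.47-fold lower (-2.90 ± 0.53, adjusted p = 0.00206), and CHST9 changed by -2.44 ± 0.69, PLPPR1 by -2.02 ± 0.42 and TMT1A by -2.02 ± 0.50. FGG, encoding a fibrinogen chain made in liver, changed by -1.44 ± 0.32, and the liver transcription factor genes ONECUT1, GATA6 and FOXA1 by -1.96 ± 0.43, -1.37 ± 0.35 and -1.34 ± 0.28. MAP2K6 changed by -2.87 ± 0.51. There were 166 genes called higher and 31 lower, while 905 genes higher and 352 lower, called or not, separated the arms (19.3% of genes, 20% by chance). After quantile normalization there were 296 and 154, so the share higher went from 84.3% to 65.8%. Without CCL set 1, 20 genes were called and 35 of 46 named calls were lost. Among these were ADH6 (adjusted p = 0.303), MAP2K6 (0.192), FOXA1 (0.544), ONECUT1 (0.808), SQSTM1 (0.633) and MT1X (0.131), and the highest adjusted p was 1 for CHST9, FMO5 and GATA6. The log2 fold change without CCL set 1 was -1.47 for ADH6, -0.80 for CHST9, -0.70 for PLPPR1, -0.73 for FGG, -0.80 for ONECUT1, -0.46 for GATA6, -0.73 for FOXA1 and -2.004 for MAP2K6. Without CCL set 2 it was, in the same order, -4.33, -4.09, -3.33, -2.16, -3.13, -2.28, -1.96 and -3.73, and without untreated set 3 it was 4.36 for IGFBP1. The count was 383 without CCL set 2 (162 higher and 221 lower), 118 without untreated set 1 and 87 without untreated set 2. Leaving out these and then untreated set 3 ended 5, 16, 20 and 6 named calls (adjusted p up to 0.263, 0.201, 0.155 and 0.118). CD109, GDF15, GPAT3, IGFBP1, IL11, JAG1, MIR3189, SAT1, SNAI2, UCA1 and VNN1 were called whichever array of the compared groups was left out.

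Metallothioneins had the highest list median at 24 h (1.33, adjusted p = 0.000295, adjusted p = 0.35 with an estimated correlation), with 3 of 5 called and 3 adjusted over the list alone. Immediate early genes rose (median 0.96, adjusted p = 1.82e-08, adjusted p = 0.35 with an estimated correlation), with 6 called and 13 adjusted over the list alone. ATF4 and CHOP targets also rose (0.78, adjusted p = 5.44e-05, adjusted p = 0.52 with an estimated correlation), with 2 called and 4 adjusted over the list alone. Autophagy and lysosome genes rose through SQSTM1 and MCOLN1 (median 0.45 over 19 genes, adjusted p = 0.000739, adjusted p = 0.644 with an estimated correlation). NRF2 targets rose through SRXN1, itself higher by 1.31 ± 0.32 (median 0.53, adjusted p = 0.00128, adjusted p = 0.588 with an estimated correlation). Gluconeogenesis genes, NF-kB targets, aminoacyl-tRNA synthetases and leukocyte markers also rose as lists (adjusted p from 0.0023 to 0.0143, the lowest being adjusted p = 0.35 with an estimated correlation). The first had IGFBP1 and PC (1.43 ± 0.33) called, and the last CD68 (1.58 ± 0.28) and LAPTM5 (1.03 ± 0.29). IGFBP1 encodes a binding protein, as stated above, and not an enzyme of gluconeogenesis. Its rise therefore does not show a higher output of that pathway. Hepatocyte transcription factors fell (median -0.40 over 8 genes, adjusted p = 0.00931, adjusted p = 0.501 with an estimated correlation), with 3 called lower and 4 adjusted over the list alone. The list of cytochrome P450 and conjugation genes, of which only FMO5, GSTA1 and GSTA2 were tested, fell (median -1.41, adjusted p = 0.012, adjusted p = 0.471 with an estimated correlation), with FMO5 alone called (-1.51 ± 0.40, or -0.28 without CCL set 1, where the adjusted p was 1, and -2.74 without CCL set 2). G1/S genes (median -0.61, adjusted p = 2.27e-07), G2 and M phase genes (-0.53, adjusted p = 8.09e-07), cholesterol genes (-0.66, adjusted p = 5.14e-06), fatty acid synthesis genes (-0.44, adjusted p = 0.000693) and DNA repair genes (-0.56, adjusted p = 0.00209) fell. For these 5 lists the lowest was adjusted p = 0.52 with an estimated correlation, and limma called 0 members over all genes. Without CCL 24 h set 1 the calls of NRF2 targets (adjusted p = 0.456), G2 and M phase genes (0.242, median 0.07), DNA repair (0.102) and autophagy genes (0.102) were lost. The call of FMO5, GSTA1 and GSTA2, none of them a P450 gene, was lost without untreated 24 h set 3 (adjusted p = 0.0514, median -0.57). The leukocyte call was lost without CCL 24 h set 2.

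**Figure D3:**
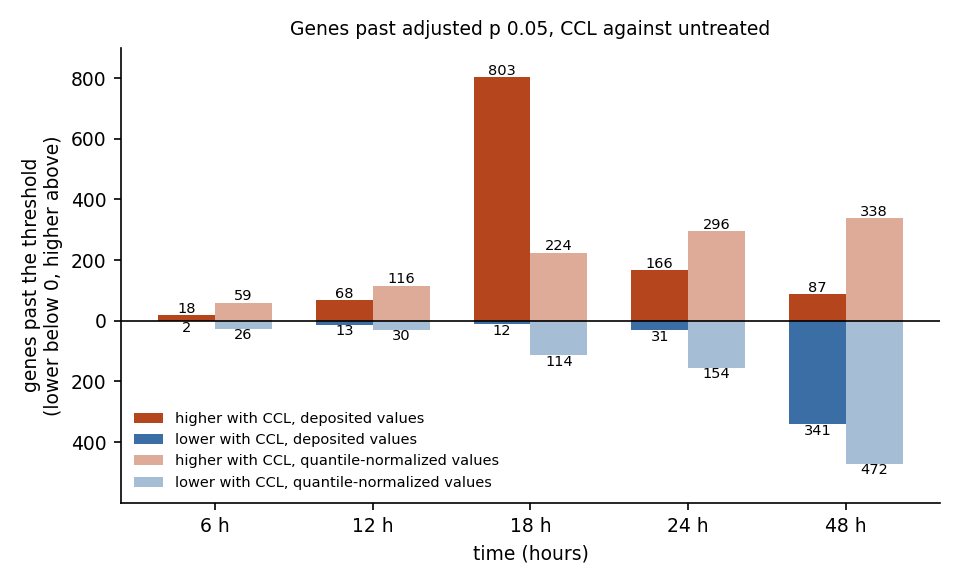
Genes called higher (above 0) and lower (below 0) with CCL at each time in h, from deposited and from quantile-normalized values, as bars. Deposited values gave 803 higher and 12 lower at 18 h and 87 higher and 341 lower at 48 h, whereas quantile-normalized values gave 224 and 114 and then 338 and 472.

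At 48 h, with all arrays used, more genes were called lower than higher, a balance that turned without CCL set 1. KIF11, of the cell cycle, changed by -2.304 ± 0.481 (2 CCL and 3 untreated arrays, adjusted p = 0.00823) and the replication genes TICRR and GINS1 by -2.49 ± 0.53 and -2.20 ± 0.47. The proliferation marker MKI67 changed by -1.97 ± 0.44, CCNB1 by -1.19 ± 0.33 and PCNA by -1.43 ± 0.32, while the median of all genes was -0.26. TXNIP fell most (-2.70 ± 0.74, adjusted p = 0.0336), with ERP27 at -2.55 ± 0.75, MIR570 at -2.33 ± 0.69 and the WNT inhibitor gene DKK4 at -2.29 ± 0.33 (adjusted p = 0.000263). Still raised were DUSP5 (3.27 ± 0.46, 9.64-fold), UCA1 (3.20 ± 0.51), VNN1 (2.75 ± 0.50), IGFBP1 (2.74 ± 0.53), IL11 (2.71 ± 0.39) and the pseudogene AQP7P3 (2.70 ± 0.43). The size of the last is uncertain, since its untreated mean of 2.65 lay below the median of all probe sets of those arrays. LAPTM5, encoding a lysosomal membrane protein, rose by 2.07 ± 0.29. Called were 87 genes higher and 341 lower, while 671 genes higher and 1927 lower, called or not, separated the arms (39.8% of genes, 20% by chance). After quantile normalization there were 338 and 472, so the share higher went from 20.3% to 41.7%. CCL set 1 decided this comparison, since without it 7 genes were called higher and 1 lower and 46 of 51 named calls were lost. The adjusted p without CCL set 1 was 1 for KIF11, TICRR, GINS1, MKI67, CCNB1, PCNA, TXNIP, ERP27 and MIR570, 0.43 for IGFBP1, 0.296 for VNN1, 0.253 for AQP7P3 and 0.0568 for DUSP5. Leaving out CCL set 1 or set 2 moved the log2 fold change to -1.04 or -3.57 for KIF11, -0.97 or -4.01 for TICRR, -0.84 or -3.56 for GINS1, -0.57 or -3.37 for MKI67, -0.45 or -1.93 for CCNB1 and -0.66 or -2.20 for PCNA. It became -1.58 or -3.83 for TXNIP, -1.24 or -3.86 for ERP27, -0.43 or -4.24 for MIR570, 2.05 or 4.49 for DUSP5 and 1.80 or 3.59 for AQP7P3. With sets 1 and 2 alone 74 genes were called higher and 18 lower. Without CCL set 2 the count was 2106 and CD109 lost its call (adjusted p = 0.0528). Leaving out untreated set 1, 2 or 3 gave 166, 85 and 109 called genes and ended 19, 27 and 24 named calls (adjusted p up to 0.107, 0.122 and 0.144). DKK4, IL11, LAPTM5 and UCA1 were called whichever array of the compared groups was left out.

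As lists, G2 and M phase genes fell at 48 h (median -1.35, adjusted p = 1.47e-11, adjusted p = 0.478 with an estimated correlation), with 16 of 23 called and all 23 adjusted over the list alone. G1/S and replication genes fell (-1.20, adjusted p = 8.29e-10, adjusted p = 0.52 with an estimated correlation), with 15 called and 19 adjusted over the list alone. DNA repair genes fell (median -1.20, adjusted p = 1.53e-05, adjusted p = 0.533 with an estimated correlation), with 7 called and 10 adjusted over the list alone. They were led by EXO1 (-1.94 ± 0.41) and XRCC2 (-1.93 ± 0.45). Splicing factors fell (median -0.91 over 18 genes, adjusted p = 7.94e-06, adjusted p = 0.559 with an estimated correlation), with 8 called and 16 adjusted over the list alone, among them SRSF1 (-1.59 ± 0.35) and TRA2B (-1.17 ± 0.27). Without CCL 48 h set 1 these lists and the ATF4 list were still called (adjusted p = 2.61e-10, 3.14e-07, 0.000832, 2.28e-05 and 3.35e-05 over the 35 lists, with adjusted p = 0.692 at the lowest with an estimated correlation). Their sizes rested on it: without CCL 48 h set 1 or set 2 the median was -0.57 or -2.09 for G2 and M phase genes, -0.42 or -1.91 for G1/S genes, -0.38 or -2.03 for DNA repair genes and -0.14 or -1.57 for cholesterol genes. EXO1, XRCC2, SRSF1 and TRA2B individually were not (adjusted p = 1). Without CCL 48 h set 1 or set 2 the log2 fold change was -0.91 or -2.97 for EXO1, -0.64 or -3.21 for XRCC2, -0.69 or -2.49 for SRSF1, -0.44 or -2.04 for EZH2 and -0.73 or -2.52 for UHRF1. Leukocyte markers rose (median 1.67 over 3 genes, adjusted p = 1.79e-05) and held with an estimated correlation (adjusted p = 0.0418, or 0.132 after quantile normalization). This came through LAPTM5 and CD68 (1.67 ± 0.28) and not LYZ (-0.02 ± 0.19), with 2 called over all genes and 2 adjusted over the list alone. Epigenetic silencing genes fell (median -0.62 over 11 genes, adjusted p = 0.0212, adjusted p = 0.667 with an estimated correlation), with EZH2 (-1.24 ± 0.33) and UHRF1 (-1.63 ± 0.42) called. Cholesterol genes fell (-0.88, adjusted p = 0.00557, adjusted p = 0.761 with an estimated correlation), with IDI1, SQLE and STARD4 called. Immediate early genes (median 0.49, adjusted p = 6.19e-07) and ATF4 and CHOP targets (0.38, adjusted p = 5.14e-06) rose (adjusted p = 0.471 and 0.478 with an estimated correlation). NF-kB targets, gluconeogenesis genes, aminoacyl-tRNA synthetases, oxidative phosphorylation genes and NRF2 targets rose with weaker calls (adjusted p from 0.00209 to 0.0479, the lowest being adjusted p = 0.471 with an estimated correlation). Oxidative phosphorylation and NRF2 targets were not called after quantile normalization (adjusted p = 0.0624 and 0.114).

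Single arrays ended several of these 48 h and 18 h list calls. Leaving out CCL 48 h set 1 ended those of cholesterol genes (adjusted p = 0.586), NF-kB targets (0.704, median -0.04), epigenetic silencing genes (0.0891), immediate early genes (0.058), NRF2 targets (0.093) and oxidative phosphorylation genes (0.054). Without CCL 48 h set 2, aminoacyl-tRNA synthetases (adjusted p = 0.0602), oxidative phosphorylation genes (0.088) and NRF2 targets (0.0848, median -0.06) were not called. Oxidative phosphorylation also lost its call without untreated 48 h set 3 (adjusted p = 0.085). NRF2 targets lost theirs without untreated 24 h set 3 (0.0514) or 48 h set 1 (0.057) or set 2 (0.0558), and without CCL 6 h set 1 (0.0514) or 12 h set 1 (0.0502) or set 3 (0.0507). Hepatocyte transcription factors at 18 h lost theirs without untreated 18 h set 1 (adjusted p = 0.0584) or set 3 (0.0708) or CCL 18 h set 3 (0.0567). Acute phase proteins lost theirs without untreated 18 h set 3 (0.148) or CCL 18 h set 1 (0.0724). WNT targets at 18 h lost theirs without untreated 18 h set 1 (0.217), untreated 24 h set 1 (0.0522), CCL 18 h set 2 (0.0545) or set 3 (0.0844), or CCL 48 h set 1 (0.0531) or set 2 (0.0506).

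**Figure D4:**
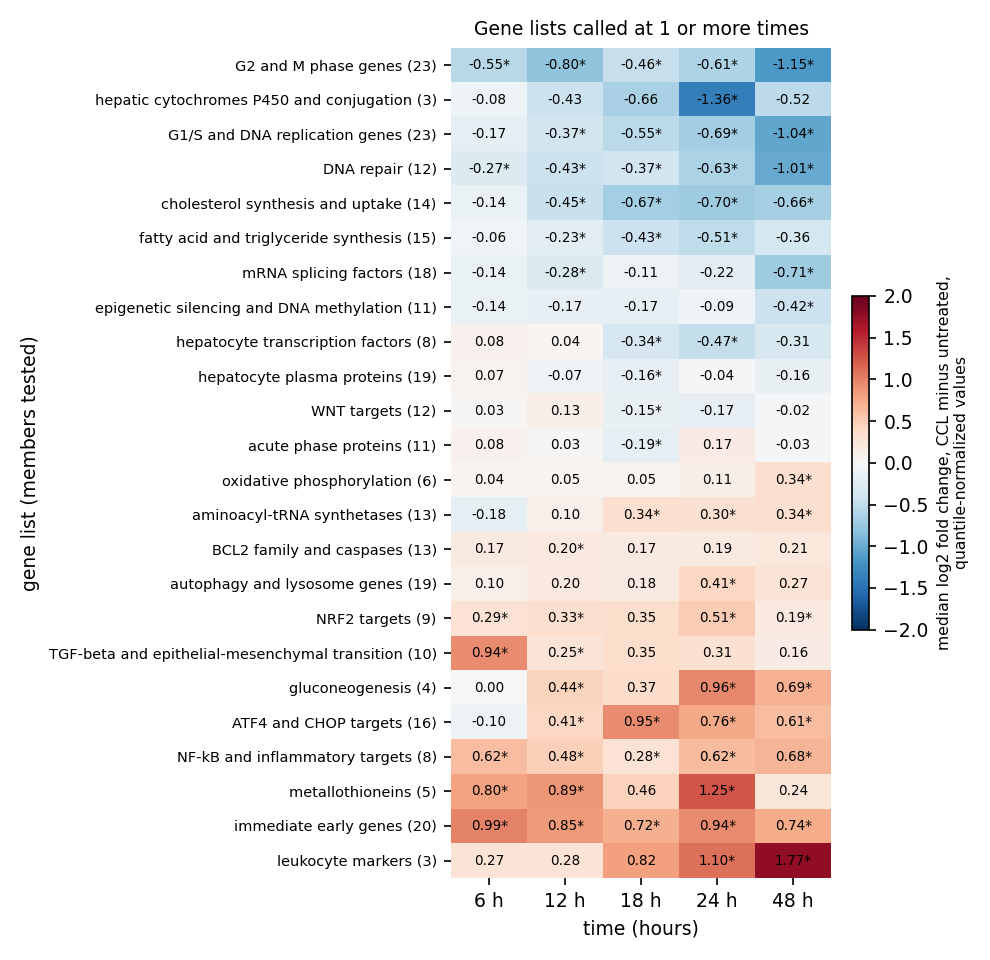
Median log2 fold change, CCL against untreated, of the 24 gene lists called at 1 or more times, by time in h, from quantile-normalized values. Colour gives the median and a star marks a call by camera on deposited values. Of the 64 starred cells, 2 were also called with an estimated correlation, and 59 were called in the same direction after quantile normalization.

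DKK4, which encodes a secreted WNT inhibitor, was the 1 gene whose response to CCL differed between the 5 times (limma F-test, adjusted p = 0.0386, 0.0127 after quantile normalization). Its difference went from 0.64 ± 0.30 at 6 h to -2.29 ± 0.33 at 48 h. In untreated cells DKK4 was 4.11 and 4.07 at 0 h and 5.35, 5.51 and 5.83 at 48 h, a difference that was not called, against 3.07 and 3.48 in CCL-treated cells at 48 h. The next genes were LAPTM5 (adjusted p = 0.436), CD109 (0.437), DLX2 (0.437), SGK2 (0.45) and HJURP (0.45). At an unadjusted p under 0.05 there were 697 genes (444 after quantile normalization). The DKK4 call held without CCL 12 h set 2 or 3, 18 h set 2, 24 h set 2 or 48 h set 2, or untreated 18 h set 3 or 24 h set 1 or 3. It was lost without any other array, with adjusted p from 0.0518 (untreated 18 h set 1) to 0.193 (CCL 48 h set 1). The count was 884 without untreated 18 h set 3, 649 without CCL 48 h set 2 and 4 without CCL 24 h set 2. EGR1 and JUNB, called at 6 h alone, and the mitotic genes called at 48 h were therefore not shown, gene by gene, to respond differently between times. The difference from 6 h was called by limma for 0 genes at 12 h, 18 h and 24 h and for 1, lower, at 48 h. After quantile normalization it was called for 0 genes at the first 3 of these times and for 1 higher and 1 lower at 48 h. At an unadjusted p under 0.05 there were 53, 1344, 329 and 364 genes in order of time, and 109, 561, 584 and 532 after quantile normalization.

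Few genes were called in untreated cells against 0 h, a comparison of times in culture that also carries the difference in array medians described above. At 12 h against 0 h, CENATAC changed by -1.98 ± 0.29 (3 and 2 arrays, adjusted p = 0.00251) and was the 1 gene also called after quantile normalization (adjusted p = 0.0237). MIR1299 (-2.58 ± 0.43), HMGN1 (-1.53 ± 0.29) and the interferon signalling gene IRF9 (-1.01 ± 0.22) were also lower. The genes of this comparison were chosen after their values were seen. In total 15 genes were called lower and 0 higher by limma at 12 h, where the median of all genes was -0.20. With set as a fixed block 146 were called lower and 0 higher. At that time 799 had an unadjusted p under 0.05 (704 after quantile normalization). The count of 15 became 1, 2 and 2 without untreated 12 h set 1, 2 or 3, 3 without 0 h set 3 and 0 without 0 h set 1, where CENATAC was lost as well (adjusted p = 0.268). MIR1299 lost its call without 0 h set 1 (-1.86, adjusted p = 0.413) or 12 h set 1 (0.0861), and was at -3.29 without 0 h set 3. HMGN1 kept its call only without 0 h set 3 among the arrays of the 2 groups (adjusted p up to 0.527), and IRF9 lost its call without any 1 of them (0.0967 to 0.527). At 6, 18, 24 and 48 h limma called 0 genes on deposited and on quantile-normalized values, with 46, 694, 320 and 82 genes at an unadjusted p under 0.05 on deposited values. After quantile normalization these were 149, 738, 699 and 270. Leaving out untreated 18 h set 3 gave 1261 genes at 18 h and leaving out untreated 24 h set 3 gave 1 at 24 h.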

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

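The comparison of lists between 48 h and 6 h and the tests of array scale and of a larger response in set 1 were chosen only after results were seen. The test of the labels of set 2 was written before its percentages were computed but after the distance between the arrays was seen.

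DKK4 was the gene whose response to CCL differed between the 5 times (adjusted p = 0.0386), being 0.64 higher at 6 h and changed by -2.29 at 48 h, while untreated cells measured 4.11 and 4.07 at 0 h and between 5.35 and 5.83 at 48 h, a difference that was not called. Without CCL 48 h set 1 the difference was not called (adjusted p = 0.193), nor without untreated 18 h set 1 (0.0518) or most other single arrays.

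Cell-cycle lists responded differently at 48 h and at 6 h. G1/S and DNA replication genes were lower by a further median of -1.03 at 48 h (adjusted p = 4.25e-12, adjusted p = 0.448 with an estimated correlation), and splicing factors by -0.79 (adjusted p = 5.36e-08, adjusted p = 0.448 with an estimated correlation). Also lower were G2 and M phase genes by -0.79 (adjusted p = 8.54e-06, adjusted p = 0.678 with an estimated correlation), DNA repair genes by -0.82 (adjusted p = 0.000549, adjusted p = 0.678 with an estimated correlation) and cholesterol genes by -0.48 (adjusted p = 0.0286, adjusted p = 0.715 with an estimated correlation). ATF4 and CHOP targets moved up between these times by 0.39 (adjusted p = 5.36e-08, adjusted p = 0.448 with an estimated correlation), and aminoacyl-tRNA synthetases by 0.23 (adjusted p = 4.56e-05, adjusted p = 0.448 with an estimated correlation). Gluconeogenesis genes moved up by 0.60 (adjusted p = 0.0207, adjusted p = 0.448 with an estimated correlation) and oxidative phosphorylation genes by 0.23 (adjusted p = 0.045, adjusted p = 0.678 with an estimated correlation). Leukocyte markers, through LAPTM5 and CD68, moved up by 1.38 (adjusted p = 3.58e-06) and held with an estimated correlation (adjusted p = 0.00826). Immediate early genes moved by -0.50 (adjusted p = 0.00922, adjusted p = 0.678 with an estimated correlation). Metallothioneins moved by -1.19 (adjusted p = 0.0348, adjusted p = 0.669 with an estimated correlation) and ER chaperones by -0.27 (adjusted p = 0.0351, adjusted p = 0.706 with an estimated correlation), the median of the former being -0.44 without untreated 6 h set 2, and neither list being called after quantile normalization (adjusted p = 0.0552 for both). Leaving out CCL 48 h set 1 or set 2 moved the median to -0.23 or -1.93 for G1/S genes, -0.03 or -1.54 for G2 and M phase genes, -0.03 or -1.71 for DNA repair genes and 0.12 or -1.09 for cholesterol genes. Without CCL 48 h set 1, G1/S (adjusted p = 0.000445), splicing (0.000171), ATF4 (0.000445), aminoacyl-tRNA synthetase (0.000289) and leukocyte lists (0.000273), immediate early genes (7.66e-19) and metallothioneins (0.000552) were still called. G2 and M phase (adjusted p = 0.528), DNA repair (0.664), cholesterol (0.523), gluconeogenesis (0.0514), ER chaperones (0.0959) and oxidative phosphorylation (0.204) were not. TGF-beta genes (7.86e-09) and NF-kB targets (4.4e-05) were then called lower at 48 h than at 6 h. Of these calls without CCL 48 h set 1, those of immediate early genes and leukocyte markers held with an estimated correlation (adjusted p = 0.0301 for both), and the others did not (adjusted p = 0.0927 for TGF-beta genes, 0.103 for NF-kB targets, 0.259 for metallothioneins, 0.591 for G1/S and 0.431 for the rest with an estimated correlation).

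Probe sets without a gene symbol also responded to CCL: of 7720 tested among 14586 probe sets above the filter, 1140 were called over the 5 times, 600 higher and 540 lower. What they measure was not analysed here.

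The CCL arrays of set 1 at 24 h and 48 h, on which many calls of ADH6, KIF11, MKI67 and other genes rested, stood apart from set 2. A scale difference left by the deposited normalization was argued against as the whole cause by values after quantile normalization. On their first component the nearer of these 2 CCL arrays lay at 33.59, beyond every other CCL array (20.92 at most). Untreated 18 h set 1, the array with the lowest median, lay at -6.53 on it, among the untreated arrays. The first component of the deposited values is a separate axis, so scores of single arrays on it are not compared with these. The SD across genes of set 1 minus set 2 was 0.557 at 24 h and 0.726 at 48 h (0.549 and 0.696 before quantile normalization). Untreated cells under a CCL label in set 2 were argued against too, as 91.4% of the 116 genes higher at 12 h lay above all untreated arrays in set 2 at 48 h (97.4% at 24 h, 25% by chance). Open is the same response at a larger size: across genes, the excess of set 1 over set 2 correlated with the mean effect at 6, 12 and 18 h at r = 0.349 at 24 h and 0.482 at 48 h (0.0758 and 0.109 for untreated cells, whose sets 1 and 2 differed with an SD of 0.487 at 24 h, nearly that of CCL cells, and 0.236 at 48 h). This may reflect a difference in exposure, and as the labels give neither dose nor culture per set, no biological explanation was tested. The SD of deposited log2 values over all probe sets was lowest in untreated 24 h set 1 (1.867) and CCL 48 h set 1 (1.897). Next were CCL 24 h set 1 (1.926) and untreated 18 h set 1 (1.956). Quality of the RNA or of the arrays was not tested, so a difference of set 1 in it is open too.

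At 18 h nearly all called genes were higher with CCL. An array scale left by the deposited normalization is a candidate explanation for that imbalance, as the share higher was 66.3% after quantile normalization against 98.5% before, and the compared arrays include both the lowest and the highest median. The 236 genes called in the same direction on both kinds of values included IGFBP1, CCL20 and SNAI2, so scale was not shown to explain the calls of these genes.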

How the results depend on the processing

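Direction never reversed for the 303 calls of named genes, among them IL11, MAP2K6 and KIF11, or for the 64 list calls by camera, under the alternatives that were run for them. Differences that were not called did turn, as that of MKI67 at 18 h from 0.25 to -0.11 after quantile normalization, and so did some list medians. The balance of genes called higher and lower did turn. At 6 h (18 and 2) it became 121 and 175 with array weights, 40 and 48 with the compared arrays alone, 93 and 105 without the 6 arrays apart, and 41 and 44, or 116 and 131 after quantile normalization, without CCL 24 h and 48 h set 1. At 12 h (68 and 13) it became 701 and 1329, 256 and 404, 282 and 492, and 99 and 117 in that order, and 60 and 445 with 0 h cells as control. At 48 h (87 and 341) it became 8 and 3 with array weights, 74 and 18 with sets 1 and 2 alone, 24 and 5 without the 6 arrays, and 9 and 2, or 16 and 4 after quantile normalization, without CCL 24 h and 48 h set 1. In the mean (885 and 721) it became 1075 and 1237 after quantile normalization, 1269 and 1413 with a set block as well, 1072 and 1262 after median centring, 592 and 720 with array weights and 634 and 901 without the 6 arrays. Without 1 array it turned at 24 h without CCL set 2, at 48 h without CCL set 1, and in the mean without CCL 18 h set 3, 24 h set 2 or 48 h set 2 or untreated 18 h or 24 h set 1. Most alternatives were set beforehand. The 5 chosen after seeing the data were leaving out the 6 arrays with a median apart, leaving out CCL 24 h set 1 and CCL 48 h set 1, quantile normalization with the latter or with a set block, and using all probe sets, named or not. Of 303 calls of named genes, 287 stayed past the threshold after quantile normalization, 288 after median centring, 303 with a fixed or a random set block, 260 without a filter, 208 with array weights, 195 with the compared arrays alone, 211 without CCL 24 h and 48 h set 1 and 197 without the 6 arrays apart. The number of called lists (57 to 75) and the median correlation between times (0.522 to 0.689) stayed near their values under the alternatives for which they were computed. Neither was for 0 h cells as control, a 2-fold minimum or all probe sets, and the lists were not for sets 1 and 2 alone. Of the 1606 genes called over the 5 times, 1592 were kept after quantile normalization, 1603 with a fixed set block, 1219 with array weights and 948 without CCL 24 h and 48 h set 1.

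At 6, 12, 18, 24 and 48 h in that order, quantile normalization gave 85, 146, 338, 450 and 810 called genes, with 1 for untreated cells at 12 h against 0 h, and median centring gave 122, 265, 372, 461 and 754, with 26 for untreated cells. A fixed set block gave 108, 257, 1571, 525 and 903, with 146 for untreated cells at 12 h and 3 in the F-test, and a random block 102, 218, 1559, 449 and 893, with 160 for untreated cells. Array weights, whose estimation did not converge, gave 296, 2030, 13, 373 and 11, with 685 and 389 for untreated cells at 12 h and 24 h. The compared arrays alone gave 88, 660, 58, 45 and 0 (limma, with 1087 genes at an unadjusted p under 0.05 at 48 h), 407 and 1 for untreated cells at 12 h and 24 h, and 0 in the F-test. Sets 1 and 2 alone gave 10, 35, 1643, 412 and 92. With 0 h cells as control, 6, 12, 18 and 24 h gave 46, 505, 156 and 67. Without a filter 18 h gave 1542, 48 h 210, untreated cells at 12 h 217 and the F-test 0. A 2-fold minimum left 501 genes at 18 h, by its construction. For untreated cells at 12 h, a trend with robust estimation gave 2 and the stricter filter 0, and both gave 0 in the F-test. For these changes the cause was not tested.

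Of the added alternatives, leaving out CCL 24 h and 48 h set 1 gave 85 at 6 h, 216 at 12 h, 23 at 24 h, 11 at 48 h, 1022 in the mean and 0 in the F-test, and with quantile normalization as well 247, 358, 494, 72 and 20 at the 5 times and 2 in the F-test. Leaving out the 6 arrays apart gave 198, 774, 59, 61 and 29, with 0 in the F-test. Quantile normalization with a set block gave 192, 282, 848 and 1190 at 6, 12, 24 and 48 h, 2682 in the mean and 3 in the F-test. All probe sets gave 2630 in the mean, from 14586 tested. The cause of these changes was not tested.

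With each array left out in turn, counts ran from 6 to 18 at 6 h, 28 to 47 at 12 h, 24 to 2647 at 18 h, 20 to 383 at 24 h, 8 to 2106 at 48 h and 1193 to 2109 in the mean. They ran from 0 to 884 in the F-test, and for untreated cells against 0 h from 0 to 0 at 6 h, 0 to 3 at 12 h, 0 to 1261 at 18 h, 0 to 1 at 24 h and 0 to 0 at 48 h. Called lists ran from 57 to 68 and the median correlation between times from 0.556 to 0.663. At 18 h the extremes came without untreated set 1 and set 3, at 24 h and 48 h without CCL set 1 and set 2, and a fold change in a group with 1 array left is that of this array. For each count of genes only the arrays of the compared groups were left out in turn, so the ranges do not cover the other arrays. Those also move a count through the shared spread. The 6 h and 12 h counts without CCL 24 h and 48 h set 1, given above, lie outside these ranges. Dim genes limit what can be seen: 6529 of 14884 named genes passed the filter, and changes of 1.5-fold were rarely recovered at single times in simulated data.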

Other observations

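The ERK, YAP and ChREBP lists below were written only after related results were seen, and the tests that reassign arrays were planned.

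AXL, encoding a receptor tyrosine kinase, was higher with CCL by a mean log2 fold change of 2.11 ± 0.13 over the 5 times (13 CCL arrays against time-matched untreated arrays, adjusted p = 1.53e-11), EPHA2, encoding an ephrin receptor, by 1.05 ± 0.10 (adjusted p = 1.6e-08), the muscle and YAP-responsive gene ANKRD1 by 1.95 ± 0.34 and the membrane repair gene MYOF by 0.95 ± 0.16. The ERK phosphatase gene DUSP6 rose by 0.75 ± 0.10. KHK, which encodes ketohexokinase, changed by -0.65 ± 0.11, TKFC, encoding a triokinase of the same fructose pathway, by -0.46 ± 0.14 and ACACB, encoding acetyl-CoA carboxylase beta, by -0.50 ± 0.15. These genes were chosen after their values were seen. In what follows, members not seen before are those outside the lists fixed beforehand and other than AXL, ANKRD1, TXNIP and ARRDC4, which prompted their lists.

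Lysosomal markers CD68 and LAPTM5, which are on the leukocyte list, rose together at 48 h (1.67 ± 0.28 and 2.07 ± 0.29) while the leukocyte lysozyme gene LYZ was unchanged within its error (-0.02 ± 0.19). Autophagy and lysosome genes were called over the 5 times with 7 members higher and 9 adjusted over the list alone (median 0.15, adjusted p = 0.00729, adjusted p = 0.605 with an estimated correlation). Contamination by other cells was not tested.

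Immediate early genes, DUSP5, SPRY4 and DUSP6 are known to follow ERK activity, so higher ERK output may be part of the response to CCL. The members not seen before (EPHA2, ETV4 and ETV5) had a median of 0.321, with EPHA2 higher and ETV5 lower (-0.39 ± 0.12), and were not called (adjusted p = 0.134 over the 3 lists tried, adjusted p = 0.251 with an estimated correlation). The list of all 7 members was called (adjusted p = 0.00416, adjusted p = 0.119 with an estimated correlation), also after quantile normalization (adjusted p = 0.0086, adjusted p = 0.0217 with an estimated correlation), but 4 of them had been seen. The 3 not seen before were not called after it either (adjusted p = 0.15). The test leaves this open.

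AXL and ANKRD1 are also YAP targets. The 7 YAP targets not seen before had a median of 0.226, 2 of them called higher (MYOF and AMOTL2), and were not called as a list (adjusted p = 0.073, adjusted p = 0.251 with an estimated correlation), and CCN2, a common YAP target, was not called (-0.35 ± 0.23). The list of all 10 was called (adjusted p = 0.0032, adjusted p = 0.119 with an estimated correlation), also after quantile normalization (adjusted p = 0.00508, adjusted p = 0.0826 with an estimated correlation). However, it includes AXL and ANKRD1, which prompted it, so this call cannot decide the question. Higher YAP output is possibly involved and stays undecided.

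TXNIP and ARRDC4 (-1.17 ± 0.18) are induced by the glucose-sensing factors ChREBP and MondoA, and MLXIPL, which encodes ChREBP, changed by -0.68 ± 0.20. Lower output of these factors is a candidate explanation. The list of all members cannot decide it, as TXNIP and ARRDC4 prompted the list. Its members ACACB, MLXIPL and PNPLA3 had also been seen, on the lists fixed beforehand. Of the 8 tested targets, 7 were called lower (median -0.66, adjusted p = 5.95e-05, adjusted p = 0.0987 with an estimated correlation), also after quantile normalization (adjusted p = 0.000299, adjusted p = 0.0217 with an estimated correlation). Of the 3 not seen before, KHK and TKFC were called lower and TM6SF2 was not, and as a list (median -0.464) they were not called (adjusted p = 0.073, adjusted p = 0.251 with an estimated correlation, and adjusted p = 0.0801 after quantile normalization). The members are too few to decide.

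The real arms stood out for the genes called over the 5 times. Of 100 assignments of arrays to arms within times, the real 1 alone gave as many as 1606 genes. The next highest gave 3 (326 against 2312 after quantile normalization). The share cannot fall below 1 of 100, and reassigning treats arrays as independent, which the labels do not show. Any other difference shared by the arrays of an arm cannot be told apart from CCL by this test. For lists, 2 of the 100 gave as many as the 18 called, the real 1 included and the highest other also giving 18, so the share was small, yet the preset correlation let an arbitrary assignment call as many lists. Taken singly, immediate early genes and NF-kB targets had as low a p in 1 of 100 assignments, the BCL2 family in 2, G2 and M phase and DNA repair genes in 4, ATF4 and CHOP targets in 6 and G1/S genes in 17. For metallothioneins it was 7, for cholesterol and gluconeogenesis genes 8, for NRF2 targets and autophagy genes 9 and for epigenetic silencing genes 10. TGF-beta genes reached it in 13, leukocyte markers in 14, fatty acid synthesis genes in 16, splicing factors in 20 and aminoacyl-tRNA synthetases in 22. At 6 h and 12 h the 10 splits of 6 arrays are too few for a share under 0.05, the real split giving 20 and 81 genes and the highest other 0 and 0.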
